A study of Homo sapiens with 12 samples.

How the data were processed

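Poly(A) RNA of NCI-H520 (H520) cells, an established human line of lung squamous cell carcinoma, was sequenced in 12 libraries, 3 for each of 4 groups: control, BLU9931 at 1 µM, palbociclib at 1 µM, and the combination of both drugs, with treatment for 72 h. BLU9931 is an irreversible, selective inhibitor of the receptor tyrosine kinase FGFR4, and palbociclib inhibits the cyclin-dependent kinases CDK4 and CDK6. The labels do not say what the control cells received, nor whether the 3 libraries of a group came from separate cultures, so the p-values may measure technical spread alone.

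The deposited table holds, per gene and library, a count, a TPM value and an FPKM value. The counts are named so per the file headers, which do not say how they were made. Their totals are whole numbers that differ between libraries. The TPM values (transcripts scaled to a fixed total) are named so per the file headers and sum to between 999907 and 999944 per library. The FPKM values (fragments scaled by gene length and library size) are named so per the file headers. The submitters' processing notes name Trimmomatic 0.36, HISAT2 2.0, bedtools 2.26.0 and StringTie 1.3.3b without saying which tool made the counts, and they name a mouse genome build. The table holds 58174 human Ensembl gene IDs, of which 57836 are in GENCODE 29 and 56033 have the same start and end there, so all positions are given on GRCh38. The annotation release, the counting mode and the use of strand are not given. The length implied by a count over its FPKM value varied between libraries, with a median log2 SD of 0.0776 and a 95th percentile of 0.2876 over the 12580 genes with at least 50 counts in every library. The table has 0 columns of samples outside the series.

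The counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1, and tables and plots were made in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9. Libraries held between 21.7 M and 35.8 M counts (M, mega). Genes were kept by edgeR's filterByExpr over the 4 groups, which left 20612 genes, 14580 of them protein-coding, of 19762 protein-coding genes in the table. Libraries were scaled by TMM, and a quasi-likelihood model (glmQLFit with robust estimation, 8 residual degrees of freedom, common dispersion 0.0518) was fitted to the 12 libraries together with a term per group. Each of 6 comparisons used edgeR's two-sided quasi-likelihood F-test with a Benjamini-Hochberg adjusted p under 0.05 and no minimum fold: each drug against control, the combination against control, against palbociclib and against BLU9931, and the interaction, which tests whether the log2 effect of the combination differs from the sum of the log2 effects of the single drugs. Levels are given as CPM, counts scaled to library size and TMM factor, as mean ± SD of 3 libraries, and log2 fold changes carry the standard error (SE) of the fit. Counting error alone did not account for the spread, since the chi-square per degree of freedom between replicates was between 17.5 and 85.6.

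The 29 gene lists were written before the data were examined, as were the comparisons, the tests and the rule for named genes. They cover DNA replication and S phase, G2 phase and mitosis, homologous recombination and Fanconi genes, G1 regulators, ERK pathway output and feedback, FGF receptors and ligands, other receptor tyrosine kinases, FOXO and PI3K feedback targets, ribosome biogenesis and MYC targets, interferon-stimulated genes, antigen presentation, secreted inflammatory factors, p53 targets, squamous and basal identity, squamous differentiation, epithelial junctions, mesenchymal genes, cholesterol synthesis, lysosome and autophagy, ATF4 and the unfolded protein response, NRF2 targets, glycolysis and hypoxia, oxidative phosphorylation, the BCL2 family and caspases, mitochondrially encoded mRNAs, and markers of neuroendocrine, lung glandular, fibroblast and leukocyte cells. A list needed at least 5 tested members. Each was tested against the other genes with camera at a preset inter-gene correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment over the 29 lists within a comparison. The oxidative phosphorylation list counts 30 gene IDs because SDHD has a pair of them.

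Named genes were a fixed panel of FGFR4, FGFR1, CCND1, CDK4, CDK6, RB1, CCNE2, E2F1, MKI67, CDKN1A, DUSP6, SPRY4, ETV4 and MYC, then per comparison the 6 largest rises and 6 largest falls among protein-coding genes past the threshold with a mean of at least 5 CPM in a compared group and no overlap between the replicates of the groups (this last condition was dropped for the interaction), the 3 members with the smallest adjusted p in each list past the camera threshold, and up to 2 members past the threshold in each other list. Fewer were printed where a comparison called many lists, and some results for single genes are not reported here. Symbols that are clone names were passed over, an edit of the rule made after the values were seen, which removed AC010132.3 from the rises under the combination. Of the 164 named genes, 105 overlap another annotated gene and 48 do so on the same strand, so that their counts depend on a strand setting that is not given. Among these 48 are FGFR1, CDK4, CDK6, RB1, SPRY4, NGFR, CFAP61, ENPP2, BCL2, IGF1R, LDHA, COL4A2 and NEURL1B.

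Alternatives chosen before the data were examined were DESeq2's size factors in edgeR, library totals without TMM, DESeq2 1.42.0 itself, limma-trend on log2 CPM with a prior count of 2 and on log2 of TPM + 1 and of FPKM + 1 (19453 and 15856 genes with a mean of at least 1 in a group), no filter on low counts, a filter of at least 1 CPM in at least 3 libraries, a fit of the compared groups alone, the replicate number as a block, a fold of at least 2, an estimated inter-gene correlation, fry in place of camera, and each library left out in turn. A GC adjustment of each library by loess (span 0.5, 20531 genes) and the omission of control 1 and palbociclib 3 together were added after the data were seen. The loess was fitted to a library's deviation from the mean of all libraries, not of its group. It can therefore also remove drug effects that follow GC content.

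The method was tested on simulated data drawn as negative binomial counts with each gene's own mean and dispersion, for 20108 genes. Of genes simulated to change 1.5-fold, 2-fold and 4-fold, 1.49%, 49.3% and 87.9% were recovered, with median estimates of 0.58, 1.06 and 2.00 on the log2 scale. Of 105 calls, 8.57% were false, and an unchanged comparison gave 0 calls. Camera detected a list of 30 genes lowered 1.5-fold, and it called 1% of 200 unchanged lists at an unadjusted threshold of 0.05. The simulated genes varied independently of each other and the lists were drawn at random. This share therefore does not cover lists whose members vary together, as those of a pathway can. The bound first set, recovery of 90% of the 4-fold changes, was not met, and it was replaced after the result was seen by a requirement on the size of the estimated folds. The 8 missed 4-fold genes had a median dispersion of 0.120, against 0.0339 in the 58 recovered. A change that did not pass the threshold is therefore not evidence of no change, also at 2-fold, and some 4-fold changes were missed too. The simulation gave 105 calls, far fewer than the larger comparisons, so its shares of recovered genes may not carry over to them.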

Results

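RNA levels were measured by poly(A) RNA sequencing in H520 cells, an established line of lung squamous cell carcinoma, in 4 groups of 3 libraries. The groups were control cells and cells given BLU9931 (an FGFR4 inhibitor), palbociclib (a CDK4 and CDK6 inhibitor) or the combination of both, each drug at 1 µM for 72 h. The control libraries 1, 2 and 3 held 28.5 M, 29.9 M and 35.8 M counts (M, mega), and the BLU9931 libraries 23.6 M, 29.5 M and 25.6 M. The palbociclib libraries held 29.3 M, 24.6 M and 24.9 M, and the combination libraries 21.7 M, 27.6 M and 30.1 M. The deposited counts of 20612 genes were compared with edgeR's quasi-likelihood test in a single fit of the 12 libraries. Levels are CPM, counts scaled to library size and TMM factor. The labels do not say that the 3 libraries of a group came from separate cultures, so the p-values may measure technical spread alone. With library totals in place of TMM, the median log2 change of all genes moved from 0.03 to at most 0.11, in the combination against control.

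Along the first principal component, with 39.5% of the variance, the control libraries (scores from -61.2 to -49.4) and the BLU9931 libraries (-46.2 to -41.6) lay on one side. The palbociclib libraries (25.5 to 34.4) lay on the other, with the combination libraries (65.3 to 67.5) beyond them. The second component, with 17.1%, set control 1 (67.4) and palbociclib 3 (71.6) apart from the other 10 libraries (-32.6 to 5.38). In these 2 libraries the deviation of a gene from its group followed its GC content, with Spearman's rho across genes of -0.667 in control 1 and -0.735 in palbociclib 3, against -0.245 to 0.600 in the other libraries. Each deviation is taken from the group mates, so the rho of the other control and palbociclib libraries (0.479 to 0.600) in part mirrors these 2. It was -0.103 to 0.0519 in the BLU9931 libraries and -0.245 to 0.404 in the combination libraries. Mitochondrially encoded transcripts took between 12% and 15.2% of the counts of a library, and the 10 most abundant genes took between 11.7% and 15%.

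**Figure D1:**
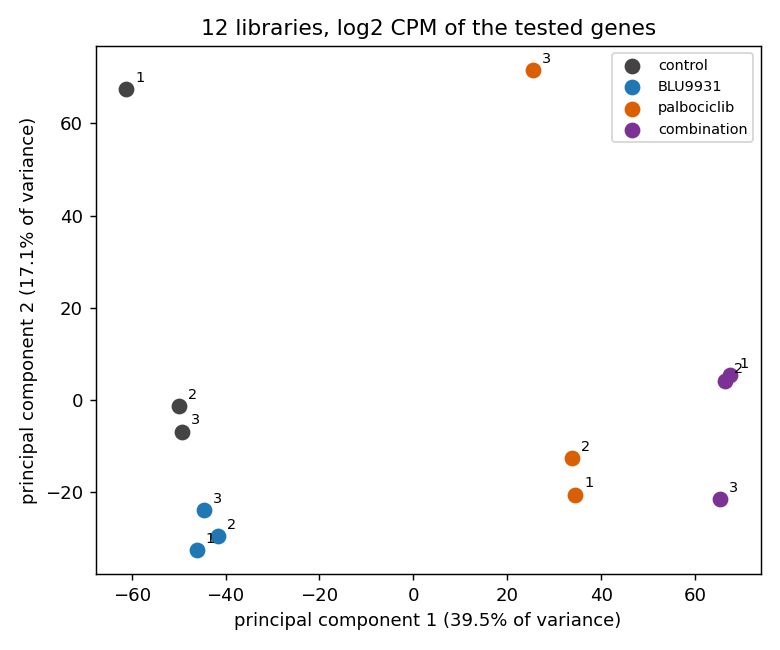
Scores of the 12 libraries on principal components 1 (39.5% of variance) and 2 (17.1%) of log2 CPM, with a point per library, its replicate number beside it and a colour per group. Control 1 (67.4) and palbociclib 3 (71.6) lie above the other 10 libraries on component 2, and the groups separate along component 1.

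Palbociclib was compared with control to ask what this drug does alone. Of the 20612 genes, 2065 rose and 2171 fell, and 1702 of these 4236 changed at least 2-fold. The balance was not stable, with 2471 rises and 1793 falls for library totals and 3029 and 4230 after a GC adjustment. The genes of DNA replication and S phase, which CDK4 and CDK6 allow to be expressed by releasing E2F factors from the RB1 protein, fell as a group. Of 46 genes, 42 fell (45 adjusted over the list alone), with a median log2 change of -0.94. GINS2 (ENSG00000131153, GRCh38 chromosome 16, 85676198 to 85690073), a part of the replicative helicase, went from 108 ± 3.17 to 37.8 ± 1.60 CPM (SD, n = 3). MCM10, which helps to activate that helicase, fell by 1.52 ± 0.12 (log2, SE). Of 34 genes of G2 phase and mitosis, 33 fell (34 adjusted over the list alone), with a median of -1.0. Among them the motor protein gene KIF2C went from 349 ± 1.05 to 164 ± 7.15 CPM and the kinetochore gene CENPF from 922 ± 105 to 357 ± 53.4 CPM (SD, n = 3). Of 20 genes of homologous recombination and the Fanconi pathway, 17 fell (19 adjusted over the list alone, median -0.95), led by the exonuclease gene EXO1 (-1.53 ± 0.13). Camera gave adjusted p values of 3.48e-27 for the replication list, 7.48e-21 for the mitosis list and 2.05e-12 for the recombination list. The last was not past the threshold, at adjusted p = 0.0719 with an estimated correlation.

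The proliferation marker MKI67 (ENSG00000148773, chromosome 10, 128096659 to 128126385) fell from 1042 ± 66.9 to 316 ± 39.5 CPM under palbociclib (SD, n = 3, log2 change -1.72, edgeR adjusted p = 0.000126). CCND1, which encodes cyclin D1, the partner of the drug's targets, rose from 278 ± 3.39 to 470 ± 17.4 CPM (adjusted p = 6.8e-05). CDK4, at 71.8 against 69.9 CPM, and RB1, at 118 against 137 CPM, did not pass the test. DUSP6 and SPRY4, feedback inhibitors induced by ERK signalling, rose by 1.04 ± 0.19 and 0.81 ± 0.12 (log2, SE), though DUSP6 did not pass on the deposited TPM (limma adjusted p = 0.143) or FPKM values (0.132). E2F1 (-0.86, adjusted p = 0.0207) and CCNE2 (-0.82, adjusted p = 0.0255) fell. E2F1 no longer passed without control 2 (adjusted p = 0.0786) or control 3 (0.0776), nor CCNE2 without control 1 (0.0903), palbociclib 1 (0.0692) or palbociclib 2 (0.0687). FGFR4 itself went from 40.7 ± 13.5 to 21.3 ± 9.95 CPM (adjusted p = 0.0722), CDKN1A from 2.98 ± 1.32 to 5.21 ± 0.723 CPM (0.0509) and CDK6 from 302 ± 56.5 to 420 ± 99.8 CPM (0.0577), none past the threshold. The spread of FGFR4 came from control 1 (25.3 CPM) and palbociclib 3 (9.86 CPM), which stood apart on the second component. The other control libraries held 46.2 and 50.6 CPM, and the other palbociclib libraries 27.4 and 26.8 CPM.

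Ribosome biogenesis genes, which MYC drives, fell under palbociclib in 17 of 25 cases (18 adjusted over the list alone, median -0.55, camera adjusted p = 1.26e-08). Among them were the snoRNP gene NOP56 (-0.75 ± 0.08) and UTP20 (-1.02 ± 0.11). Of 22 interferon-stimulated genes, 11 rose and 1 fell (12 and 1 adjusted over the list alone, median 0.60, adjusted p = 6.54e-06). The RNA exonuclease gene ISG20 rose from 5.02 ± 0.452 to 15.2 ± 0.272 CPM (SD, n = 3) and IFI27 from 55.6 ± 9.58 to 119 ± 13.5 CPM. Of 23 cholesterol synthesis genes, 9 fell and 1 rose (12 and 1 adjusted over the list alone, median -0.55, adjusted p = 0.000369), led by ACAT2 (-0.98 ± 0.14). Of 23 ATF4 and unfolded protein response genes, 9 fell and 2 rose (11 and 2 adjusted over the list alone, median -0.45, adjusted p = 0.00428). The serine synthesis genes PSAT1 (-1.11 ± 0.14) and PHGDH (-0.83 ± 0.13) led this list. Of 30 lysosome and autophagy genes, 9 rose and 1 fell (10 and 1 adjusted over the list alone, median 0.30, adjusted p = 0.00445), but adjusted p = 0.194 with an estimated correlation. The phosphoinositide-binding gene WIPI1 rose by 1.03 ± 0.12. Oxidative phosphorylation genes had a median of -0.19, with 6 of 30 falling and 1 rising, also when adjusted over the list alone (camera adjusted p = 0.0224). This call ended with library totals (0.0714), without control 1 (0.0529), and at adjusted p = 0.385 with an estimated correlation.

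Rises under palbociclib were ranked among protein-coding genes with a mean of at least 5 CPM in a compared group and no overlap between replicates. The largest were those of the muscle protein gene SMPX (3.84 ± 0.24), of SSPO (3.61 ± 0.48) and of ENPP2 (3.50 ± 0.22), which encodes the secreted phospholipase autotaxin. The transporter genes SLC18A2 (3.49 ± 0.25), SLC9A4 (3.43 ± 0.16) and SLC26A9 (3.12 ± 0.17) followed. ENPP2 (ENSG00000136960, chromosome 8, 119557086 to 119673453) went from 1.81 ± 0.512 to 20.6 ± 1.80 CPM (SD, n = 3). Under the same limits, the largest falls were those of ZNF551 (-3.07 ± 0.60) and of the growth factor gene FGF4 (ENSG00000075388, chromosome 11, 69771016 to 69775403), which went from 15.4 ± 3.57 to 2.08 ± 0.336 CPM (-2.88 ± 0.23, edgeR adjusted p = 1.44e-05). In other lists, BTG2, an antiproliferative p53 target, rose from 24.1 ± 2.42 to 206 ± 9.98 CPM (adjusted p = 6.27e-08), and TP53INP1 by 2.89 ± 0.23. The FOXO targets SESN3 (2.25 ± 0.21) and TXNIP (0.97 ± 0.09) and the binding protein gene IGFBP5 (1.69 ± 0.10) rose too. The receptor genes KIT (-1.64 ± 0.13) and ERBB3 (-1.29 ± 0.14) and the glycolysis gene LDHA (-1.65 ± 0.20) fell. ZNF551 counts jumped more than 4-fold between replicates of BLU9931 and are uncertain. Its fall did not pass with control 1 and palbociclib 3 both left out (edgeR adjusted p = 0.0511).

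BLU9931 was compared with control to ask what this drug does alone. Whether FGFR4 was inhibited in these cells was not measured. Of the 20612 genes, 29 rose and 8 fell, 24 of these 37 at least 2-fold, while 3347 genes had an unadjusted p under 0.05. FGFBP1 (ENSG00000137440, chromosome 4, 15935569 to 15938740), which encodes a carrier that releases FGFs from the matrix, rose from 7.14 ± 0.845 to 19.7 ± 0.504 CPM (SD, n = 3, log2 change 1.46 ± 0.12, edgeR adjusted p = 0.00195). It alone among the named genes passed the test with any of the 12 libraries left out. CHAC1, a glutathione-degrading enzyme gene, rose from 2.79 ± 0.599 to 13.3 ± 2.08 CPM (adjusted p = 0.0256). The neurotrophin receptor gene NGFR rose from 4.38 ± 1.14 to 14.9 ± 0.923 CPM (0.0169), and the choline transporter gene SLC44A2 from 39.9 ± 4.52 to 111 ± 5.43 CPM (0.0207). POLR3F, an RNA polymerase III subunit gene, fell from 10.5 ± 2.48 to 3.41 ± 0.787 CPM (0.0381), and PLCXD1 from 16.0 ± 1.05 to 6.99 ± 1.17 CPM (0.0207). Without control 1, 2 or 3 or BLU9931 1, 2 or 3, the adjusted p was 0.0566 to 0.145 for CHAC1, 0.0607 to 0.124 for SLC44A2, 0.0708 to 0.174 for POLR3F and 0.0501 to 0.102 for PLCXD1. For NGFR it was 0.0569 to 0.0708 without any of these except control 1. Leaving out palbociclib 2 (CHAC1 0.0517, POLR3F 0.0556), combination 1 (CHAC1 0.0532, POLR3F 0.0568), combination 2 (CHAC1 0.0507, SLC44A2 0.0515, POLR3F 0.0755, PLCXD1 0.0517) or combination 3 (POLR3F 0.0771) also ended calls.

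The count of 37 genes rested on single libraries. It was 12, 3 and 7 without control 1, 2 and 3, and 1, 7 and 7 without BLU9931 1, 2 and 3. It was 17, 10 and 15 without combination 1, 2 and 3, 17 without palbociclib 2 and 396 without palbociclib 3. With both control 1 and palbociclib 3 left out it was 553, and with a GC adjustment 765. The excess of rises was lost with DESeq2 (281 rose, 333 fell) and with the GC adjustment (310 and 455), and was small without palbociclib 3 (208 and 188). None of the 14 panel genes passed the test under BLU9931. FGFR4 was at 53 ± 1.07 CPM against 40.7 ± 13.5 in control (SD, n = 3, log2 change 0.38, edgeR adjusted p = 0.563) and DUSP6 at 91.5 ± 14.3 against 70.6 ± 14 (0.348). ETV4, an ERK-induced transcription factor gene, was at 26.8 ± 1.49 against 18.4 ± 5.28 (0.291), CCND1 at 247 ± 9.08 against 278 ± 3.39 (0.304) and MKI67 at 1150 ± 60.3 against 1042 ± 66.9 (0.702). Control 1 lowered the control means of FGFR4 and ETV4, at 25.3 and 12.3 CPM. Control 2 and 3 held 46.2 and 50.6 CPM of FGFR4 and 21.4 CPM each of ETV4. The ERK output list had a median of 0.06 over 20 genes, with 0 past the test (1 rose adjusted over the list alone, camera adjusted p = 0.467). The FGF receptor and ligand list had a median of 0.20 over 22 genes, with FGFBP1 past the test in both ways of adjusting (0.455). Ribosome biogenesis genes were lower as a group, with a median of -0.29 over 25 genes, 0 past the test over all genes and 13 falling when adjusted over the list alone (camera adjusted p = 2.3e-05, 0.0177 with an estimated correlation). DNA replication genes had a median of -0.16 (0.0232), lost without BLU9931 2 (0.0876) or BLU9931 3 (0.072), and adjusted p = 0.485 with an estimated correlation. In this list 0 of 46 passed the test, also when adjusted over the list alone.

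The combination was compared with control to ask for the joint effect of both drugs. Of the 20612 genes, 3174 rose and 3358 fell, 3183 of these 6532 at least 2-fold. The balance was not stable: rises made up 48.6% of the calls, but 55.7% of 6674 with library totals. Of 46 genes of DNA replication and S phase, 45 fell (46 adjusted over the list alone) with a median of -1.77. All 34 genes of G2 phase and mitosis fell, also when adjusted over the list alone, with a median of -2.60. Camera gave adjusted p values of 1.21e-34 and 6.15e-33. MKI67 fell to 63.4 ± 18.9 CPM (SD, n = 3, log2 change -4.04 ± 0.21, edgeR adjusted p = 2.15e-07). The mitotic kinesin gene KIF20A (ENSG00000112984, chromosome 5, 138178719 to 138187715) fell from 151 ± 9.07 to 9.34 ± 1.04 CPM (-4.01 ± 0.12, 6.05e-09). TYMS, which encodes the thymidylate-making enzyme, went from 74.6 ± 2.09 to 7.10 ± 0.929 CPM, and MYBL2, a transcription factor gene of late S phase, from 244 ± 30.4 to 16.8 ± 2.43 CPM. All 20 recombination and Fanconi genes fell, also when adjusted over the list alone (median -1.95, camera adjusted p = 5.71e-17). EXO1 (-3.14 ± 0.14) was among them. CCNE2 went from 34.5 ± 9.52 to 5.03 ± 0.239 CPM (adjusted p = 8.03e-06) and E2F1 from 77.3 ± 20.5 to 26.5 ± 3.55 CPM (0.000412). CCND1 rose to 504 ± 34.0 CPM (8.53e-06) and the CDK inhibitor gene CDKN1A to 8.04 ± 1.01 CPM (0.00164).

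In the combination, ribosome biogenesis genes fell in 16 of 25 cases, also when adjusted over the list alone (median -0.58, camera adjusted p = 1.64e-05), with NOP56 at -1.02 ± 0.08. Of 22 interferon-stimulated genes, 10 rose and 1 fell (14 and 1 adjusted over the list alone, median 0.71, 0.00277). ISG20 reached 17.2 ± 2.16 CPM and the signalling gene STAT2 at 72.2 ± 7.18 CPM against 36.0 ± 2.06 in control (SD, n = 3). Of 30 lysosome and autophagy genes, 12 rose and 1 fell (14 and 1 adjusted over the list alone, median 0.59, 0.00104), with adjusted p = 0.143 with an estimated correlation. The cholesterol carrier gene NPC2 rose by 1.33 ± 0.11. Cholesterol synthesis genes fell in 10 of 23 cases and rose in 1, also when adjusted over the list alone (median -0.29, 0.0144), with adjusted p = 0.0586 with an estimated correlation. Under the limits set for named genes, the largest falls were those of the laminin gene LAMA1 (ENSG00000101680, chromosome 18, 6941744 to 7117814, -5.74 ± 0.46), the WNT inhibitor gene DKK2 (-5.02 ± 0.26) and the lipase gene LPL (-4.50 ± 0.21). LAMA1 went from 6.72 ± 0.696 to 0.111 ± 0.135 CPM. With the same limits, and with the clone name AC010132.3 passed over, the largest rises were those of the phosphatase gene DUSP15 (5.38 ± 0.49), ADIPOQ (4.90 ± 0.64), ITIH6 (4.88 ± 0.40), TSPAN1 (4.02 ± 0.29) and GSX1 (4.0 ± 0.37). DUSP15 was at 0.122 ± 0.114 CPM in control. No control library exceeded 0.298 CPM for ADIPOQ, 0.396 for ITIH6 or 0.554 for TSPAN1. The folds of these genes, DUSP15 included, are poorly bounded. FGFR4 was at 21.8 ± 1.03 CPM (-0.90, edgeR adjusted p = 0.0607). DUSP6 rose by 0.78 ± 0.19 but did not pass on TPM (limma adjusted p = 0.29) or FPKM values (0.267). ETV4 fell by 0.76 ± 0.24 (edgeR adjusted p = 0.0297), a call that ended without control 2 (0.107), control 3 (0.104), combination 1 (0.0853), combination 2 (0.098) or combination 3 (0.0534).

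**Figure D2:**
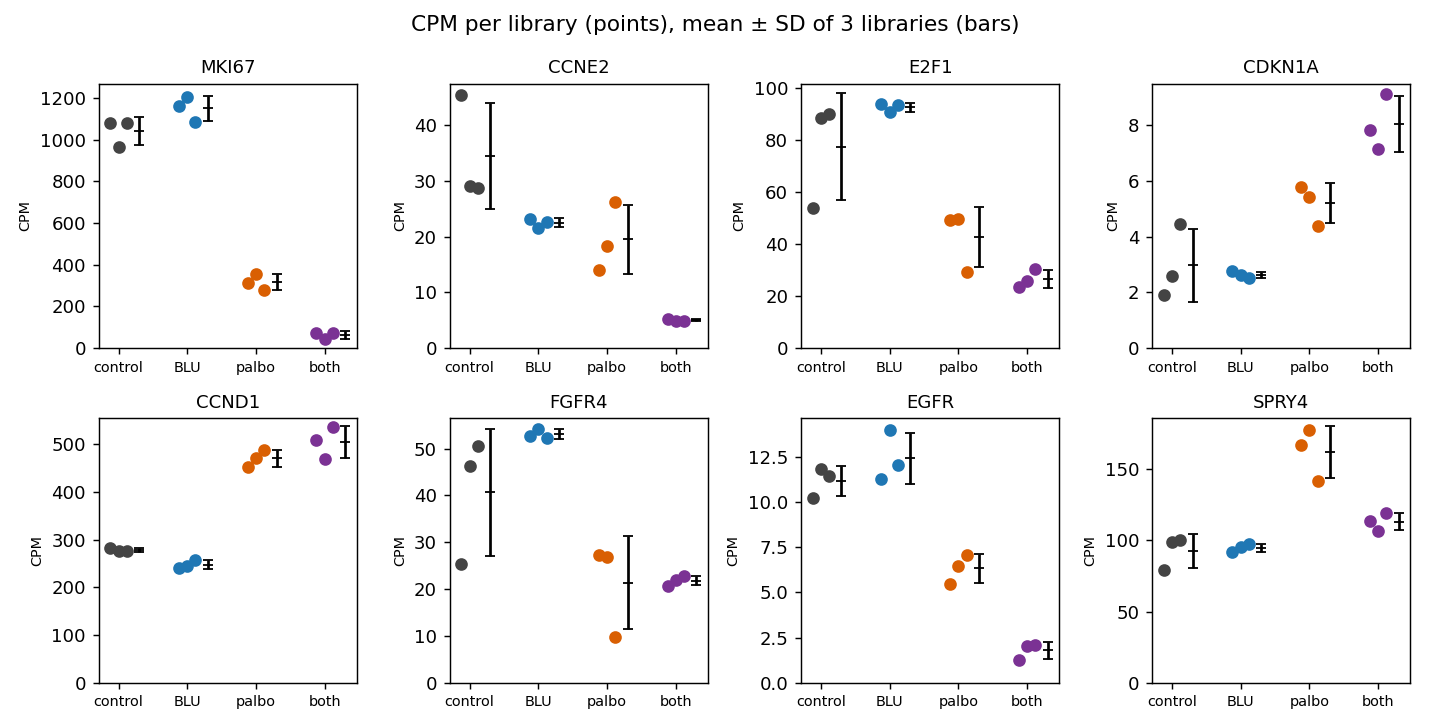
CPM of 8 genes in the 4 groups, with a point per library and, beside the points, the mean ± SD of 3 libraries. MKI67 went from 1042 CPM in control to 316 with palbociclib and 63.4 with both drugs, while the BLU9931 libraries stood at 1150.

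The combination was compared with palbociclib to ask what BLU9931 adds in the presence of palbociclib. Of the 20612 genes, 189 rose and 599 fell, 397 of these 788 at least 2-fold. The count was 438, 442 and 452 without combination 1, 2 and 3. The excess of falls was lost with the GC adjustment (1287 rose, 1229 fell) and was smaller with control 1 and palbociclib 3 both left out (817 and 1226). Mitotic genes fell further, 32 of 34 (33 adjusted over the list alone), with a median of -1.61 (camera adjusted p = 2.16e-55). KIF20A fell from 61.6 ± 2.33 to 9.34 ± 1.04 CPM (SD, n = 3, edgeR adjusted p = 5.16e-07), and the securin gene PTTG1 from 83.2 ± 3.93 to 20.5 ± 1.08 CPM. Of 46 replication genes, 32 fell (44 adjusted over the list alone, median -0.75, 7.86e-43). RRM2, a subunit gene of the enzyme that makes deoxyribonucleotides, fell from 48.7 ± 7.69 to 9.54 ± 0.735 CPM. Of 20 recombination genes, 15 fell (17 adjusted over the list alone, median -1.02, 3.45e-21). MKI67 fell by 2.32 ± 0.19 (log2, SE) and CCNE2 by 1.96 ± 0.24. NRF2 targets rose in 5 of 21 cases (8 adjusted over the list alone, median 0.28, camera adjusted p = 2.96e-07). The quinone reductase gene NQO1 rose from 394 ± 15.7 to 568 ± 12.7 CPM and AKR1C1 from 714 ± 18.5 to 1219.5 ± 15.8 CPM. AKR1C1 and AKR1C2 are near-identical copies whose counts are uncertain.

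Of 19 other receptor tyrosine kinase genes, 5 fell and 0 rose in the combination against palbociclib, also when adjusted over the list alone (median -0.30). EGFR (ENSG00000146648, chromosome 7, 55019021 to 55211628), an epidermal growth factor receptor gene, went from 6.33 ± 0.810 to 1.81 ± 0.467 CPM (SD, n = 3, edgeR adjusted p = 0.000366). IGF1R went from 1.76 ± 0.365 to 0.556 ± 0.170 CPM (0.00319) and KIT from 27.0 ± 4.04 to 16.4 ± 1.06 CPM (0.00767). IGF1R did not pass on TPM values (limma adjusted p = 0.45), and with only the compared groups fitted neither did IGF1R (edgeR adjusted p = 0.0636) nor KIT (0.0975). The list's camera adjusted p was 0.0257, but 0.0955 without palbociclib 2, 0.0842 without palbociclib 3, and adjusted p = 0.257 with an estimated correlation. The lysosome list (median 0.15, 1 of 30 rising, also when adjusted over the list alone) passed at 0.0258, but not without palbociclib 3 (0.138) or combination 3 (0.0745), and had adjusted p = 0.364 with an estimated correlation. The oxidative phosphorylation list (median 0.12, 0 of 30 past the test, also when adjusted over the list alone) passed at 0.0257, but not without palbociclib 1 (0.0528), palbociclib 3 (0.0512) or combination 3 (0.0907), and had adjusted p = 0.432 with an estimated correlation. FGFBP1 rose from 6.50 ± 0.248 to 15.8 ± 0.824 CPM (edgeR adjusted p = 0.000126), as it had with BLU9931 alone. DUSP15 rose by 5.07 ± 0.48 and DKK2 fell by 5.17 ± 0.26, to 0.162 ± 0.0196 CPM. DUSP15 did not exceed 0.236 CPM in any palbociclib library, so its fold is poorly bounded. FGFR4 stood at 21.8 against 21.3 CPM, a log2 change of 0.03 that turned to -0.31 with control 1 and palbociclib 3 both left out.

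**Figure D3:**
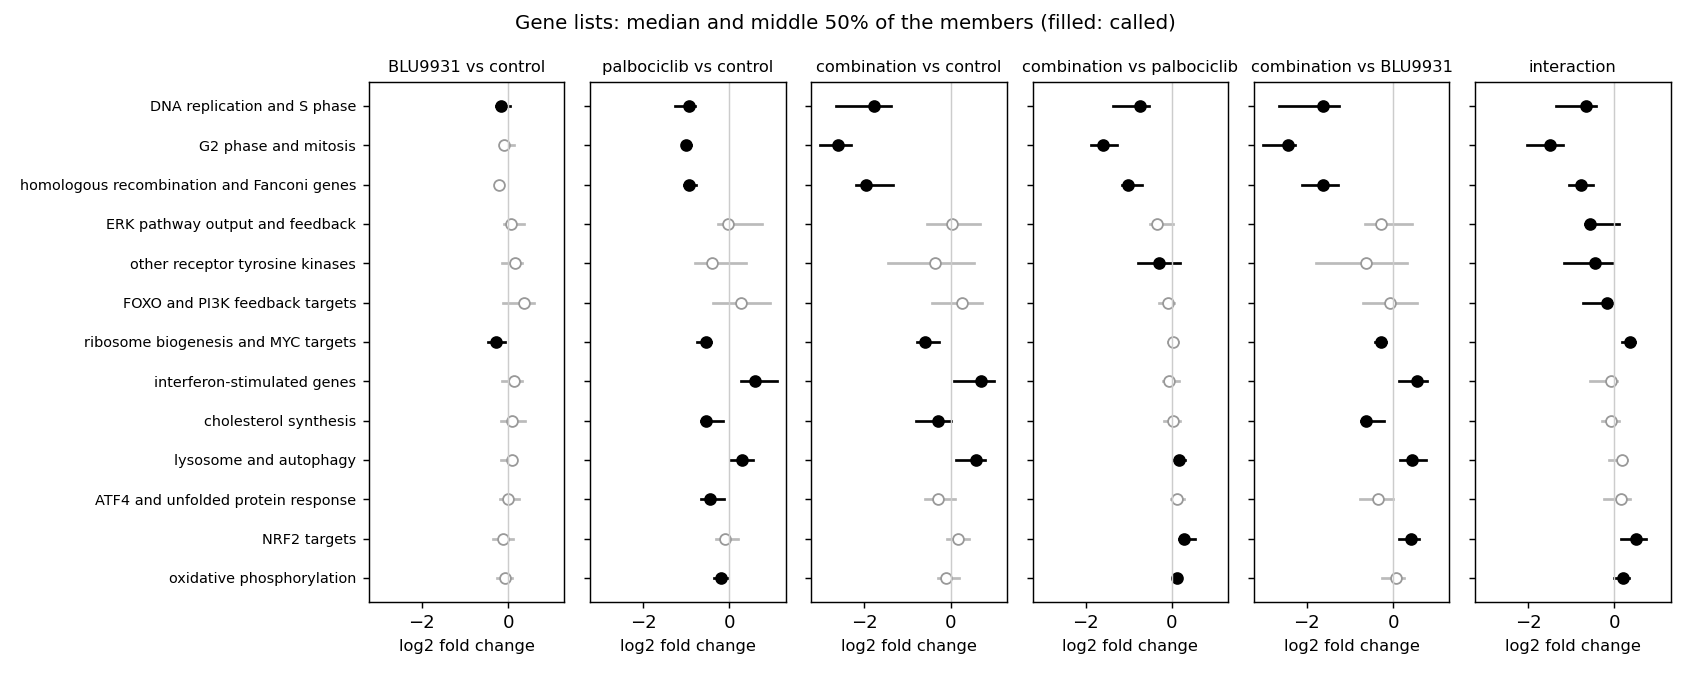
Median (circle) and middle 50% (line) of the log2 fold changes of the members of 13 gene lists, with a panel per comparison, and filled circles for lists past the camera threshold. The median of the G2 phase and mitosis list was -1.0 with palbociclib and -2.60 with the combination, against -0.09 with BLU9931.

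The combination was compared with BLU9931 to ask what palbociclib does in the presence of BLU9931. Of the 20612 genes, 2751 rose and 2821 fell, 2643 of these 5572 at least 2-fold. Rises made up 49.4% of the calls, and 52.0% of 5687 with library totals. In this comparison 44 of 46 replication genes fell, also when adjusted over the list alone (median -1.62, camera adjusted p = 1.65e-35). All 34 mitotic genes fell, also when adjusted over the list alone (median -2.43, 1.27e-35), and 18 of 20 recombination genes fell, also when adjusted over the list alone (median -1.63, 1.06e-16). MYBL2 fell from 275 ± 12.7 to 16.8 ± 2.43 CPM and KIF2C from 383 ± 15.9 to 39.5 ± 3.39 CPM (SD, n = 3). Of 21 NRF2 targets, 10 rose and 0 fell (11 and 1 adjusted over the list alone, median 0.41, 0.00149), with adjusted p = 0.0533 with an estimated correlation. Cholesterol synthesis genes fell in 11 of 23 cases (13 adjusted over the list alone, with 1 rising, median -0.62, 0.000215), led by FDPS, a prenyl diphosphate synthase gene (-1.15 ± 0.10). Interferon-stimulated genes rose in 9 of 22 cases and fell in 1 (10 and 1 adjusted over the list alone, median 0.56, 0.00417). Lysosome genes rose in 13 of 30 cases and fell in 1, also when adjusted over the list alone (median 0.43, 0.000656), with adjusted p = 0.111 with an estimated correlation. Ribosome biogenesis genes fell in 6 of 25 cases (7 adjusted over the list alone, median -0.29, 0.0134), with adjusted p = 0.0533 with an estimated correlation. FGFR4 fell from 53 ± 1.07 to 21.8 ± 1.03 CPM (edgeR adjusted p = 0.0152), a call that ended without combination 1 (0.0574) or combination 2 (0.0518). Under the limits set for named genes, the largest changes were the rises of ITIH6 (4.42 ± 0.39) and ADIPOQ (4.06 ± 0.60) and the falls of LAMA1 (-6.00 ± 0.46) and C1QL1 (-5.82 ± 0.61), the last at 0.103 ± 0.0921 CPM in the combination. Neither ITIH6 nor ADIPOQ exceeded 0.541 CPM in a BLU9931 library. Their folds, and those of LAMA1 and C1QL1, are poorly bounded.

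The interaction was tested to ask whether the combination's effect differs from the sum of the single-drug effects on the log2 scale. It passed in 328 genes, 270 below the sum and 58 above it. The excess below the sum was lost with the GC adjustment (887 below, 1061 above), which can also remove drug effects that follow GC content. It was smaller with control 1 and palbociclib 3 both left out (1136 and 981) or palbociclib 3 alone (600 and 386). Mitotic genes lay below the sum in 28 of 34 cases (32 adjusted over the list alone), with a median of -1.49 (camera adjusted p = 1.11e-44). Replication genes lay below it in 15 of 46 (34 adjusted over the list alone, median -0.67, 4.88e-25). For KIF20A the interaction was -2.79 ± 0.15 (log2, SE, edgeR adjusted p = 8.91e-06). BLU9931 alone left it at 158 ± 11.5 CPM (SD, n = 3), palbociclib at 61.6 ± 2.33 and both drugs at 9.34 ± 1.04, from 151 ± 9.07 in control. MKI67 had an interaction of -2.46 ± 0.26 (0.000739) and the mitotic scaffold gene IQGAP3 (ENSG00000183856, chromosome 1, 156525405 to 156572604) of -3.21 ± 0.23 (4.2e-05). CCNE2 (-1.34, 0.0729) and E2F1 (-0.95, 0.198) did not pass. EGFR (-1.95 ± 0.27, 0.00383) lay below the sum, and the NRF2 targets (median 0.50, 4 of 21 above it, 8 adjusted over the list alone, camera adjusted p = 8.52e-08) lay above it. The count of 328 was 169 and 189 without control 2 and 3, and 148, 182 and 187 without BLU9931 1, 2 and 3. It was 213, 196 and 986 without palbociclib 1, 2 and 3, and 184, 164 and 200 without combination 1, 2 and 3.

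**Figure D4:**
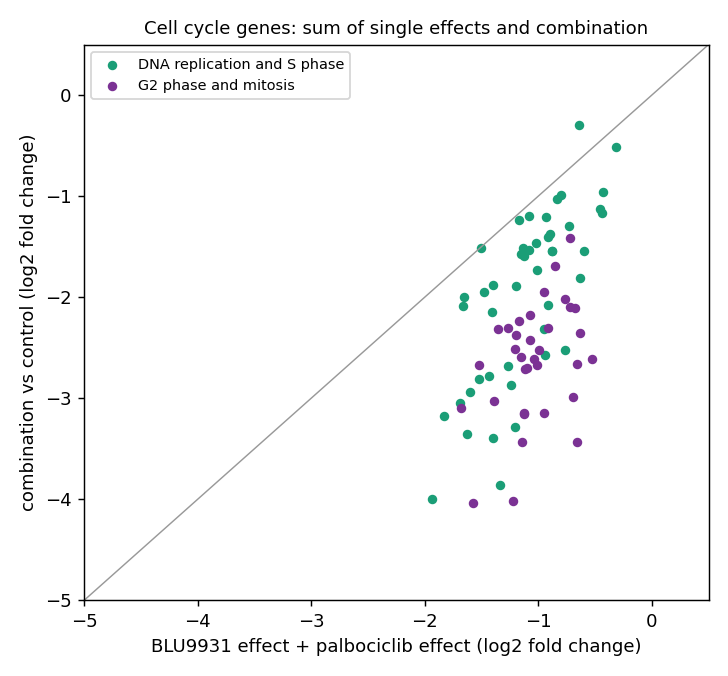
Log2 fold change of the combination against control (vertical) plotted on the sum of the log2 fold changes of BLU9931 and of palbociclib against control (horizontal), with a point per gene of the replication list (46) or of the mitosis list (34); the line marks equality. All 34 mitosis genes lie below the line, with a median distance of -1.49.

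Each drug's effect was also compared with and without the other drug across the 20612 genes, between contrasts that share no library. Genes are not independent replicates, so no p is given. For palbociclib, Pearson's r was 0.623 and Spearman's rho 0.636. Of 2829 genes past the threshold in both contrasts, 2816 moved in the same direction, where 573 genes shared in the same direction would arise if the calls were unrelated. For BLU9931, r was 0.092 and rho 0.144. Of 18 genes past the threshold in both contrasts, 14 moved in the same direction, among them FGFBP1, where 0.498 would arise if the calls were unrelated. With control 1 and palbociclib 3 both left out, 75 of 147 such genes moved in the same direction, so nearly as many moved in opposite directions. After the GC adjustment 135 of 231 did. The numbers if the calls were unrelated were 26.5 and 46.5, but these count only genes shared in the same direction. An excess over them can come from genes that are called in both contrasts in either direction. It does not show that the directions agree. The r of BLU9931 was -0.04 without palbociclib 3, 0.038 without control 1, 0.036 without combination 3 and 0.144 without palbociclib 1, so that its sign and size rested on single libraries. With control 1 and palbociclib 3 both left out, r was -0.011 and rho -0.058. These libraries deviated alike, and each contrast subtracts the group that holds one of them. A positive r is therefore not evidence of a shared effect of BLU9931.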

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

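The tests of a swap of labels, of cells of another type, of reads divided between overlapping genes and of counts estimated from isoforms were chosen only after the result was seen.

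The results of this paragraph and the next were singled out by the test of the interaction, that is, by an effect of the combination that differs from the sum of the log2 effects of the single drugs; 328 genes passed it (edgeR's quasi-likelihood test, Benjamini-Hochberg). Among gene lists past the camera threshold, the median interaction was -0.67 for DNA replication and S phase, -1.49 for G2 phase and mitosis and -0.77 for homologous recombination and Fanconi genes, of which 6 of 20 passed (15 adjusted over the list alone, camera adjusted p = 1.75e-11), but adjusted p = 0.121 with an estimated correlation. It was 0.36 for ribosome biogenesis (0 of 25 past the gene test, also when adjusted over the list alone, camera adjusted p = 9.12e-05), 0.50 for NRF2 targets and 0.20 for oxidative phosphorylation (0 of 30, also when adjusted over the list alone, 0.0041, and adjusted p = 0.265 with an estimated correlation). The medians of ERK pathway output and feedback (-0.56), other receptor tyrosine kinases (-0.46) and FOXO and PI3K feedback targets (-0.16) passed at 0.0439, 0.00655 and 0.0439, and not at adjusted p = 0.141, 0.141 and 0.128 with an estimated correlation. In these lists 1 of 20, 2 of 19 and 0 of 20 genes lay below the sum (6, 5 and 0 adjusted over the list alone, with 1 ERK gene above it). The ERK list did not pass without control 1 (0.11) or 3 (0.0896), BLU9931 1 (0.0604), 2 (0.0689) or 3 (0.0833), palbociclib 2 (0.144) or 3 (0.168), or combination 1 (0.0644), 2 (0.144) or 3 (0.0521). The kinase list did not pass without palbociclib 3 (0.0612), and the FOXO list not without control 2 (0.0637) or 3 (0.0746), BLU9931 1 (0.0533) or 3 (0.0526), palbociclib 2 (0.107) or 3 (0.0874), or combination 1 (0.0642).

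Below the sum lay the cell cycle genes MKI67 (-2.46), MYBL2 (-2.52), TYMS (-1.99), RRM2 (-2.09), KIF20A (-2.79), KIF2C (-2.19), PTTG1 (-2.03), RAD54L (-1.43), EXO1 (-1.37), PIF1 (-3.30), IQGAP3 (-3.21) and the CDK inhibitor gene CDKN2C (-1.99). So did the matrix and secreted protein genes LAMA1 (-5.11), DKK2 (-4.18), C1QL1 (-3.78), COL4A2 (-2.56) and THBS1 (-0.63), the receptor genes EGFR (-1.95) and IGF1R (-1.48), and NEURL1B (-3.93), PHLDA1 (-2.79), THY1 (-2.42), NDRG1 (-2.17) and OAS3 (-1.17). Above the sum lay SENP3-EIF4A1 (4.47), PSME3 (2.91), ZNF589 (2.19), C11orf57 (1.97), ZNF678 (1.89), SMOC1 (1.87), AKR1C1 (0.90), SRXN1 (0.74), AKR1C2 (0.64) and HK2 (0.60). The calls of CDKN2C, C1QL1, IGF1R, NEURL1B, PHLDA1, THY1, THBS1, SENP3-EIF4A1, PSME3, C11orf57, SMOC1, SRXN1 and HK2 ended when single libraries were left out, with adjusted p values between 0.0503 (NEURL1B without palbociclib 2) and 0.138 (IGF1R without combination 2). LAMA1, ZNF589, ZNF678, RAD54L, EXO1, AKR1C2, OAS3 and NDRG1 did not pass on the deposited TPM and FPKM values, with limma adjusted p values between 0.0562 (OAS3, FPKM) and 0.636 (ZNF678, FPKM). LAMA1 and C1QL1 were near 0 in the combination (0.111 and 0.103 CPM), so their interactions are poorly bounded. Counts of SENP3-EIF4A1 (18.9, 38.9 and 119 CPM in the combination) and NEURL1B (4.80, 25.4 and 29.9 CPM in control) jumped more than 4-fold between replicates, and both results are uncertain.

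The genes of G2 phase and mitosis fell further as a group under both drugs than the single effects add up to. Most replication and recombination genes did not pass the interaction test over all genes, and the checks that follow cover the mitosis list alone. The tables argue against the libraries that stand apart as the cause, since the median interaction of the mitosis list stayed at -1.47 (upper quartile -1.16) with control 1 and palbociclib 3 both left out. They also argue against GC content, with -1.52 (upper quartile -1.20) after a GC adjustment. With library totals the median was -1.54 (upper quartile -1.25). The TMM factors lay between 0.942 and 1.03, so this swap could move the median little and cannot decide on the scaling between libraries. A joint effect of BLU9931 and palbociclib that is more than additive on the log2 scale may explain the pattern. Whether it passes through FGFR4 was not tested. The mRNA levels of a whole culture cannot tell fewer cycling cells from less mRNA per cycling cell. Of 100 splits of the 12 libraries into 4 groups, the real one included, 2 gave at least as many interaction genes as the real 328. These splits mix libraries with and without palbociclib and can carry its effect into the interaction, so their share does not test the count. The highest other gave 2351, several times the real count. It sets 5 of the 6 libraries with palbociclib and 1 control library against the rest. In 8 other splits that part the palbociclib libraries in this way, 0 or 1 gene passed the adjusted threshold. At an unadjusted edgeR p under 0.05 these held 2774 to 4748 genes, against 6508 in the highest split and 2937 in the real one. Their low adjusted counts therefore do not argue against a palbociclib effect carried into the interaction.

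Control 1 and palbociclib 3 stood apart from their groups, with root mean square deviations of 0.673 and 0.745 (log2) from their group mates against 0.488 to 0.572 in the other libraries, and their deviations correlated across genes (r = 0.464). GC content of the transcripts may account for part of this: Spearman's rho with GC was -0.667 in control 1 and -0.735 in palbociclib 3. A swap of these labels is argued against by the score of control 1 on the axis from the other control to the other palbociclib libraries, -0.0717, with palbociclib 3 at 0.759 (6004 genes). Cells of another type cannot be told apart from none, since the highest of the 4 medians of fibroblast and leukocyte markers was -0.0102 with an SE of 0.30 over 6 markers, the others being -0.449, -0.319 and -0.0819. No biological explanation was tested, because the labels give none that would join these libraries.

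Counts of 431 genes jumped more than 4-fold between replicates of a group, among them MYC, which lay between 2.83 and 35.2 CPM in control. Reads divided between overlapping genes on the same strand do not account for all of them, since 53.4% of the 431 overlap such a gene, against 33.8% of the 12630 others. In jump genes without such an overlap, counts estimated from transcript isoforms are a candidate explanation: the log2 SD of the implied length was 2.71 times as large (0.212 in 195 genes) as in 1617 genes matched on expression (0.0784). No biological explanation was tested for this pattern.

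For the comparisons of 3 libraries with 3, the 10 possible splits are too few for a share under 0.05, and in each the real split alone, 1 of 10, gave as many genes as it did. With only the compared groups fitted, the real count and the highest other were 6 and 4 for BLU9931 against control, 1839 and 2 for palbociclib against control, 6287 and 1 for the combination against control, 297 and 5 against palbociclib, and 8038 and 1 against BLU9931. At an unadjusted edgeR p under 0.05, the real split of BLU9931 and control held 3606 genes, against 362 to 520 in the others. For the combination against palbociclib the real split held 2482 and the highest other 2502.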

How the results depend on the processing

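The GC adjustment and the omission of control 1 and palbociclib 3 together were chosen after seeing the data; the other alternatives were planned. The count of genes past the threshold in BLU9931 against control (37) was 17 without a filter on low counts, 71 with the stricter filter, 614 with DESeq2, 18 on TPM and 63 on FPKM, 6 with only the compared groups fitted, 553 with both libraries left out, 765 with the GC adjustment, 24 with a fold of at least 2, and 1 to 396 with each library left out in turn. Palbociclib against control (4236) gave 1839 with only the compared groups, 7259 with the GC adjustment, 1702 with a fold of at least 2 and 2985 to 5689 with each library left out. The combination against control (6532) gave 3183 with a fold of at least 2 and 5105 to 7869 with each library left out. Against palbociclib (788) it gave 1314 with DESeq2, 297 with only the compared groups, 2043 with both libraries left out, 2516 with the GC adjustment, 397 with a fold of at least 2 and 438 to 945 with each library left out. Against BLU9931 (5572) it gave 8685 with both left out, 8447 with the GC adjustment, 2643 with a fold of at least 2 and 4120 to 6836 with each library left out. The interaction (328) gave 863 with DESeq2, 2117 with both left out, 1948 with the GC adjustment and 148 to 986 with each library left out. The GC adjustment moved the share of rises from 48.7% to 41.7% in palbociclib against control, from 78.4% to 40.5% in BLU9931 against control, from 24.0% to 51.2% in the combination against palbociclib and from 17.7% to 54.5% in the interaction. A fold minimum lowers a count by construction. The GC adjustment may also have removed drug effects that follow GC content. Apart from the fold minimum, the cause was not tested.

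With the replicate number as a block, the counts were 2 for BLU9931 against control, 483 for the combination against palbociclib and 142 for the interaction. The numbers do not pair the libraries: the 18 pairs with the same number across groups had correlations of their deviations from -0.364 to 0.168, 3 of them over 0.1, and 4 of 12 libraries were closest to a library of their own number.

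The lists past the threshold in BLU9931 against control (2) were 1 with an estimated correlation, 4 with fry, 4 with both libraries left out and 1 to 4 with each library left out. Fry, which does not compare a list with other genes, gave 16 for palbociclib against control (9), 22 for the combination against control (7), 11 against palbociclib (7) and 17 against BLU9931 (8). An estimated correlation gave 4 against palbociclib, 5 against BLU9931 and 4 for the interaction (9), and each library left out gave 4 to 8 against palbociclib. Of 42 list results, 25 kept their call with an estimated correlation, 42 with the GC adjustment and 38 with both libraries left out.

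The correlation across genes of the BLU9931 effect with and without palbociclib (r = 0.092) was 0.255 over genes past the threshold, 0.041 with the GC adjustment, reversed at -0.011 with both libraries left out, and -0.0358 to 0.144 with each library left out. That of palbociclib (0.623) was 0.744, 0.686 with the stricter filter, 0.533 with both left out, and 0.530 to 0.581 with each library left out. Of the 387 results for named genes, DESeq2 ended 0 calls, limma-trend on CPM 4, TPM 45, FPKM 34, the block 35, only the compared groups 33, and each library left out between 6 and 38; TPM, FPKM and only the compared groups covered fewer than the 387. NDUFA9 under palbociclib (-0.36) turned to 0.0042 on TPM and 0.018 on FPKM values, and FGFR4 in the combination against palbociclib (0.03) to -0.31 with both libraries left out; the cause was not tested. The alternative pseudocount was not run, because the counts need none. In these libraries of 21.7 M to 35.8 M counts the spread between replicates was larger than counting error. What limits the calls was not tested.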

Other observations

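Several lists moved in both directions and did not pass the camera threshold. Where no second count is given, the count adjusted over the list alone was the same. Under palbociclib, 4 of 18 p53 targets rose and 3 fell (6 and 3 adjusted over the list alone, median 0.29, adjusted p = 0.125), and under the combination 6 rose and 4 fell (7 and 4, 0.273). Of 23 BCL2 family and caspase genes, 4 rose and 2 fell with palbociclib (4 and 3 adjusted over the list alone, 0.773), among them the pro-apoptotic gene BBC3 (2.61 ± 0.35, log2, SE) upward and PMAIP1 (-1.75 ± 0.27) downward; with both drugs 7 rose and 3 fell (0.412), and the anti-apoptotic gene BCL2 went from 6.23 ± 1.03 to 0.740 ± 0.320 CPM (SD, n = 3, edgeR adjusted p = 1.79e-05). Of 25 glycolysis and hypoxia genes, 4 rose and 5 fell with palbociclib (4 and 8 adjusted over the list alone, 0.426), with ENO1 at -0.79 ± 0.08, and 4 rose and 9 fell with both drugs (6 and 9 adjusted over the list alone, 0.377). Mesenchymal genes went 4 up and 4 down of 23 with palbociclib (5 and 6 adjusted over the list alone, 0.838) and 5 up and 9 down with both drugs (0.412), where the basement membrane collagen gene COL4A2 fell from 35.1 ± 7.25 to 4.35 ± 0.434 CPM (SD, n = 3). Epithelial junction genes went 3 up and 2 down of 19 with palbociclib (5 and 3 adjusted over the list alone, 0.953), with the cadherin gene CDH1 at 0.87 ± 0.15.

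Under palbociclib, 20.6% of all tested genes passed the test, and the lists of identity markers did not pass the camera threshold. Of 15 squamous and basal genes, 1 rose and 1 fell (4 and 3 adjusted over the list alone, camera adjusted p = 0.838), the keratin gene KRT15 going from 4.21 ± 0.933 to 13.7 ± 2.28 CPM (SD, n = 3). Of 8 squamous differentiation genes 1 rose (0.492), and with both drugs 4 (median 0.72, 0.172). Of 10 neuroendocrine genes 2 rose and 2 fell (0.887); the granule gene CHGB went from 388 ± 18.2 to 728 ± 66.5 CPM. None of 5 lung glandular genes (0.773), of 6 fibroblast genes (2 rose adjusted over the list alone, 0.92) or of 13 mitochondrially encoded mRNAs (0.953) passed, and 2 of 6 leukocyte genes rose (0.2), LYZ reaching 1.57 ± 0.393 CPM. With both drugs 2 leukocyte genes rose against control (median 0.46, 0.206) and 3 against BLU9931 (0.87, 0.202), 1 fibroblast gene fell against control (-0.36, 0.504) and 2 against BLU9931 (-0.62, 1 rose and 2 fell adjusted over the list alone, 0.382). Of the mitochondrially encoded mRNAs 2 fell against control (-0.25, 1 adjusted over the list alone, 0.273), 1 rose and 1 fell against BLU9931 (0.94) and 1 fell against palbociclib (-0.27, 0.0707), where 1 fibroblast gene fell too (-0.42, 0.17). Under palbociclib, of 16 antigen presentation genes, 4 rose and 1 fell (5 and 1 adjusted over the list alone, 0.269); HLA-C counts are shared between near-identical genes and are uncertain. Of 9 secreted inflammatory factors, 1 rose and 1 fell (0.92), and of 19 G1 regulators 1 rose and 3 fell (4 and 4 adjusted over the list alone, 0.773), with CDK2 at -1.12 ± 0.14. The ERK output list had 5 rises and 1 fall among 20 genes (6 and 2 adjusted over the list alone, 0.466), the FGF receptor and ligand list 2 and 3 among 22 (0.838), the other receptor tyrosine kinases 3 and 5 among 19 (5 and 5 adjusted over the list alone, 0.582), the FOXO targets 6 and 3 among 20 (9 and 5 adjusted over the list alone, 0.327) and the NRF2 targets 2 and 4 among 21 (0.737).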
